A study of Mus musculus with 10 samples.

How the data were processed

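RNA was extracted from mouse livers with Sepazol, fragmented and labelled with biotin using an Affymetrix terminal labelling kit for whole transcripts, per the labels' protocols. The authors deposited 1 table of intensity values on a linear scale, with 28815 probe sets for each of the 10 arrays. The values ran from 18.4 to 29834 and none was missing. Mouse genome build mm8 is named in the submitters' processing notes. How the arrays were background-corrected, normalized and summarized is not given in the sources used here. At each rank, the arrays lay within 0.213 on the log2 scale of their mean, so they had nearly but not exactly the same distribution. Whether a background remains in the values is unknown, and any such background would shrink fold differences of dim genes.

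Genes were named through the platform table. Of the probe sets, 21780 had 1 gene symbol, 1605 had several and 5430 were not named there; those with several or none were left out of gene-level tests. The symbols of 21689 probe sets were updated through their gene ID in a RefSeq gene table (assembly GRCm38.p6), and 91 kept the platform's symbol. That table belongs to another build than the notes name, so it served only for names and for gene order. Where a gene had several probe sets, as 998 did, the probe set with the highest mean over all arrays was used, which left 19935 genes.

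Genotype and replicate number came from the sample titles, with 5 arrays per genotype. Each title names a separate liver, and the labels state nothing more on litters or cages. The 2 most similar arrays differed by a root mean square of 0.165 on the log2 scale, so no array was a copy of another. The values were taken to log2 as deposited, with no filter on dim genes, and NML-KO was compared with WT by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Rrp8 was also tested by an exact permutation of the mean difference.

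Lists of genes, 22 of pathways and liver functions and 12 of cell type markers, were fixed before the data were examined, as was the rule for named genes. The main tests and alternatives were fixed then too, but not those stated below to have been chosen after values were seen. Each list with at least 5 measured members was tested against all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 34 lists, and again with the correlation estimated from the arrays. Named genes were Rrp8; in each direction the 8 genes past the threshold with the largest differences and no overlap, filled up by the smallest unadjusted p since too few passed, leaving out predicted genes and gene families without specific names; the 2 members of each list with the smallest p; and 6 sex and strain markers, of which Ddx3y had no probe set with a single gene. Hspb1, Trim30d, Gm1966 and members of the clock list other than Alas1 and Per1 were named after their values had been seen.

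The arrays were sorted into 2 sets by the sign of the first principal component of log2 values centred within genotype. This split was made after seeing the data, is not a label of the study, and was used as a term in the model or to recalculate each difference within a set. Alternatives tried were quantile normalization, median centring, a trended and robust prior, array weights, leaving out dim genes, the mean of all probe sets of a gene, all probe sets, an offset of 16 before log2, the replicate number as a block, each array left out in turn, other thresholds, other list tests and other windows around Rrp8.

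The gene fit and the list test were tested on simulated data for the comparison of NML-KO with WT, with normal errors of the observed spread for 19935 genes, 200 of them changed in each of 10 simulations. At an adjusted p below 0.05, 19.8% of genes changed 1.2-fold were recovered, 65.6% at 1.5-fold, 91.6% at 2-fold and 97.4% at 4-fold, with 7.5 false calls per simulation. Of 100 simulated lists of 30 genes shifted by 0.15 on the log2 scale, camera called 100, and it called 1 of 100 lists that were not shifted. These simulations held no array sets and no correlation between genes. Their 200 changed genes also ease the Benjamini-Hochberg threshold, so recovery would be lower where only a few genes change.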

Results

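Total RNA from the livers of 12-week-old mice was measured on whole-transcript microarrays, with 5 wild-type (WT) animals and 5 animals lacking nucleomethylin (NML-KO), 1 array per liver. Nucleomethylin is the product of Rrp8, a nucleolar protein that takes part in silencing ribosomal RNA genes, and the comparison asks which liver transcripts differ when it is missing. The arrays had similar median intensities, from 62.5 to 66.7, and the number of arrays limits the precision of every value.

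The signal of Rrp8 was lower in every NML-KO liver. Its mean log2 intensity was 7.75 ± 0.11 (SD, n = 5) in WT livers and 6.87 ± 0.22 (SD, n = 5) in NML-KO livers, so that the NML-KO signal was 54.5% of the WT signal (95% confidence interval from limma, 46.5% to 63.8%). All 5 NML-KO livers lay below all 5 WT livers, with WT values from 7.65 to 7.90 and NML-KO values from 6.65 to 7.19 (probe set 10566516). The difference of -0.88 (SE 0.10) had p = 0.0079 in a two-sided exact permutation test, the smallest that all assignments of the arrays to genotypes can give, and ranked first of 19935 genes by limma, with a Benjamini-Hochberg adjusted p of 0.109. NML-KO 4 had the highest Rrp8 value of its group, and without that array limma's adjusted p was 0.0171. The part of the gene removed in these mice and the part read by the probes are not given in the sources used here, so the remaining signal does not measure intact transcript.

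**Figure D1:**
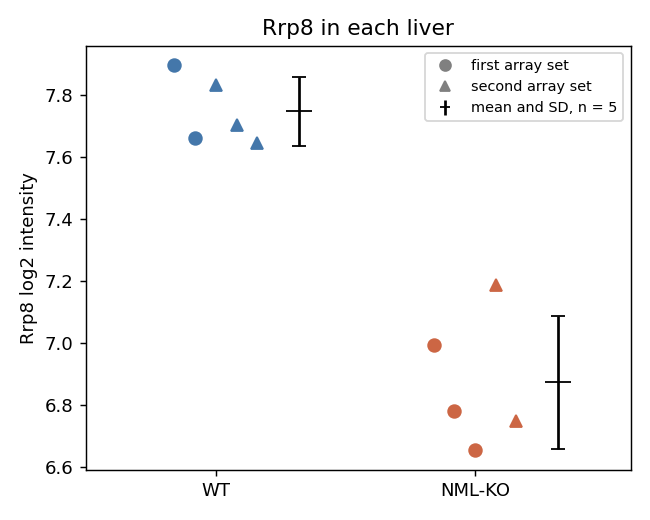
Log2 intensity of Rrp8 in each of the 10 livers (points), with the mean and SD of each genotype beside them (n = 5). The symbols mark the array sets described in the text, and the NML-KO values of 6.65 to 7.19 all lie below the WT values of 7.65 to 7.90.

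The livers also differed strongly in a way that cut across genotype. WT 1, WT 2 and NML-KO 1 to 3 formed a first set of arrays, and WT 3 to 5 with NML-KO 4 and NML-KO 5 a second, on a component that held 51.1% of the variance within genotypes. Transcripts of the circadian clock followed these sets: Dbp, a transcription factor under direct clock control, lay between 9.68 and 10.2 in the first set and between 6.20 and 6.60 in the second. Arntl, which encodes the clock activator BMAL1, lay between 5.55 and 5.90 in the first set and between 8.10 and 8.27 in the second. The labels give no time of dissection and no processing batch, so the counts, Rrp8 and the lists past the threshold are also given with the array set as a term or within each set. For Rrp8 the difference was -0.97 in the first set and -0.76 in the second, and -0.87 with the array set in the model (adjusted p = 0.179 by limma).

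**Figure D2:**
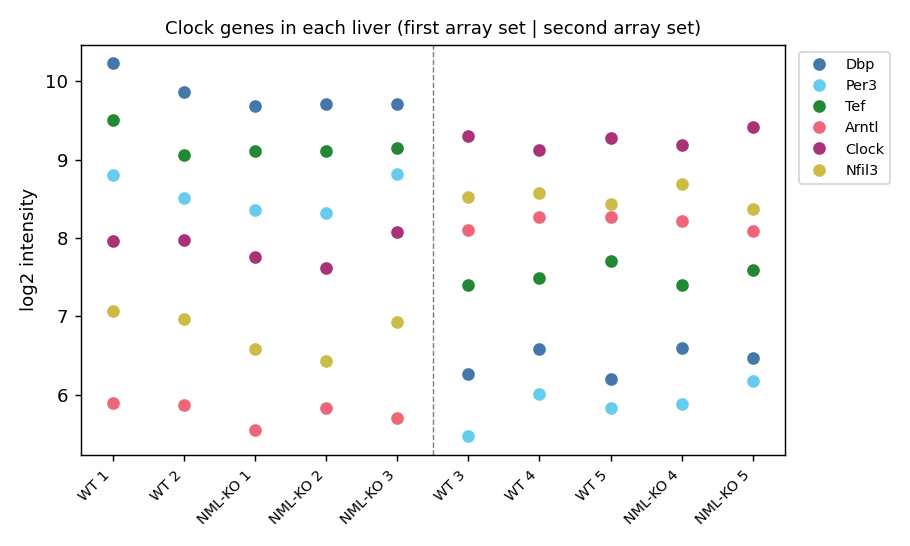
Log2 intensity of 6 clock genes in each liver, with the first array set on the left of the dashed line and the second on the right. Dbp fell between 9.68 and 10.2 on the left and between 6.20 and 6.60 on the right, with both genotypes on each side.

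Across the genome, 0 of 19935 genes passed an adjusted p of 0.05 in limma, and 539 (2.70%) had an unadjusted p below 0.05, 209 higher and 330 lower in NML-KO livers. The count past the adjusted threshold was also 0 with the array set in the model, where 870 genes had an unadjusted p below 0.05, and 0 within each array set. The groups did not overlap for 27 genes that were higher and 54 that were lower, 0.406% of genes, against 0.794% by chance for 5 against 5.

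None of the genes named next passed the threshold, and they were taken for their small unadjusted p. All 15 of them had the same sign in both array sets, which the choice by a small p over the same arrays makes likely. Of the 8 higher genes, Cabyr, which encodes a calcium-binding protein best known from sperm, had the widest difference at 2.87-fold (log2 difference 1.52, SE 0.36), although its genotypes overlapped. Gtf2e1, a subunit of the general transcription factor TFIIE, was 1.33-fold higher, and Zfp971, a zinc finger gene, was also 1.33-fold higher. Hace1, a ubiquitin ligase gene, Xkr8, a phospholipid scramblase gene, Ubtd1, Ypel1 and Cebpd, a transcription factor gene of the C/EBP family, were 1.18-fold to 1.25-fold higher. Apart from Rrp8, the lower genes were led in size by Cib3 (1.82-fold, log2 difference -0.87, SE 0.18), Trim12a (1.77-fold, with -0.52 in the first array set and -1.22 in the second) and Hnf4aos (1.68-fold), an antisense transcript of the hepatocyte factor gene Hnf4a. The array value of Cib3 in WT 2 lay apart from the other WT values. For Trim12a and Pde4c, as for Cabyr, the genotypes overlapped. Lrrc32 was 1.44-fold lower, and Strn4, Pde4c and Ttll13 were 1.18-fold to 1.23-fold lower, Strn4 with WT 1 apart from the other WT livers. Trim12a, Lrrc32, Strn4 and Ttll13 lie on chromosome 7, as does Rrp8, while Cib3 and Pde4c lie on chromosome 8 and Hnf4aos on chromosome 2. Chromosome 7 held 1733 of the tested genes besides Rrp8, against 18119 on other chromosomes. The log2 difference was larger in the first array set than in the second for Strn4 (-0.44 and -0.15), Pde4c (-0.37 and -0.20), Ypel1 (0.48 and 0.21) and Xkr8 (0.31 and 0.15). It was smaller in the first for Gtf2e1 (0.27 and 0.48) and Ubtd1 (0.15 and 0.36).

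As groups, 7 of the 34 gene and marker lists lay apart from other genes in limma's camera test with its preset correlation, 5 lower and 2 higher in NML-KO livers. None of the 7 passed when the correlation between members was estimated from the arrays, where the smallest adjusted p was 0.620. None of their members passed the threshold over all genes.

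Cytosolic ribosomal protein genes were lower as a group, with 47 of 54 measured members below 0 and a median log2 difference of -0.15 (camera adjusted p = 1.56e-09; adjusted p = 0.818 with an estimated correlation). Of these, 6 had an unadjusted p below 0.05, all lower, and 0 passed when adjusted over the list alone. Rpl36, a protein of the large subunit, was 1.32-fold lower (SE 0.14 on the log2 scale), at -0.66 in the first array set and -0.050 in the second. Rps9, of the small subunit, was 1.13-fold lower with no overlap between genotypes, at -0.27 in the first array set and -0.066 in the second. The group's median was -0.27 in the first array set and 0.023 in the second. Ribosomal protein genes have many processed copies in the genome, so their probe sets can read more than 1 locus.

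Heat shock protein genes were higher, with 13 of 14 measured members above 0 and a median of 0.16 (camera adjusted p = 1.04e-05; adjusted p = 0.620 with an estimated correlation). The 5 members with an unadjusted p below 0.05 were all higher, and 4 passed when adjusted over the list alone. Hspa1a, an inducible HSP70 gene, was 1.40-fold higher (log2 difference 0.48, SE 0.13) with no overlap between genotypes, although its sequence is nearly that of Hspa1b. Hsph1, an HSP110 gene, was also 1.40-fold higher (SE 0.16), and Hspb1, a small heat shock protein gene, was the single member below 0, at -0.49 (SE 0.45). The median was 0.27 in the first array set and 0.26 in the second, and 0.079 without NML-KO 5 (camera adjusted p = 0.0103).

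Interferon-stimulated genes were lower, with 28 of 31 members below 0 and a median of -0.23 (camera adjusted p = 1.04e-05; adjusted p = 0.818 with an estimated correlation). Bst2, an antiviral membrane protein gene, was 1.34-fold lower and Mx2 1.28-fold lower, with log2 differences of -0.59 and -0.58 in the first array set and -0.088 and -0.056 in the second. 3 members had an unadjusted p below 0.05, and 0 passed when adjusted over the list alone. The median was -0.29 in the first array set and 0.0068 in the second, -0.12 without NML-KO 2 (camera adjusted p = 0.0327) and -0.35 without NML-KO 4 (2.29e-12). The list mean above that of all genes was lowest in NML-KO 2 (0.19) and highest in NML-KO 4 (1.05), and the mean of Kupffer cell and macrophage markers was also lowest in NML-KO 2 (0.86) and highest in NML-KO 4 (2.11), with a median difference of -0.21 in the first array set and 0.22 in the second.

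Genes of cholesterol synthesis and uptake were lower, with 19 of 21 members below 0 and a median of -0.40 (camera adjusted p = 0.000321; adjusted p = 0.818 with an estimated correlation). Cyp51, the sterol demethylase gene, was 1.48-fold lower (SE 0.29 on the log2 scale) and Lss, the lanosterol synthase gene, 1.32-fold lower (SE 0.20), with log2 differences of -0.12 and -0.14 in the first array set and -0.75 and -0.51 in the second. No member had an unadjusted p below 0.05, and 0 passed when adjusted over the list alone. The median was 0.083 in the first array set and -0.55 in the second, and -0.22 with the array set in the model (camera adjusted p = 0.00316). Without WT 4 it was -0.23, with a camera adjusted p of 0.0720, and without WT 5 it was -0.23, with 0.0286.

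Oxidative phosphorylation genes had a median of -0.076 with 52 of 73 members below 0 (camera adjusted p = 0.00682; adjusted p = 0.818 with an estimated correlation). Ndufc2, of complex I, was 1.16-fold lower (-0.054 in the first array set and -0.35 in the second), while Ndufa1, of the same complex, was 1.15-fold higher with no overlap between genotypes. The list did not pass without WT 4 (camera adjusted p = 0.201), NML-KO 2 (0.0915) or NML-KO 4 (0.0506), and its median was -0.072 in the first array set, -0.028 in the second, -0.038 with the array set in the model (0.0437), -0.046 without WT 4 and -0.036 without NML-KO 2. Acute phase and inflammation genes had a median of 0.13 with 28 of 35 members above 0 (camera adjusted p = 0.0490; adjusted p = 0.818 with an estimated correlation). Steap4, a metalloreductase gene, was 1.77-fold higher (SE 0.29 on the log2 scale), with log2 differences of 0.37 in the first array set, 1.24 in the second and 0.55 without NML-KO 4, and the chemokine gene Ccl3 was 1.11-fold lower. NML-KO 4 had the highest acute phase mean above that of all genes (3.82 against 1.87 to 2.54 in the other livers), and also the highest means of neutrophil and marrow granulocyte markers (-0.82 against -1.45 to -1.28) and of Kupffer cell and macrophage markers (2.11 against 0.86 to 1.76). The acute phase median was -0.063 in the first array set, 0.48 in the second and 0.27 with the array set in the model (camera adjusted p = 1.99e-06). It was -0.10 without NML-KO 4, 0.083 without WT 2, and 0.21 without WT 5, 0.22 without NML-KO 1, 0.25 without NML-KO 2 and 0.20 without NML-KO 3; the call was lost without NML-KO 4 (camera adjusted p = 0.0506) and without WT 1, WT 2, WT 3 or NML-KO 5 (camera adjusted p = 0.325, 0.0846, 0.0904 and 0.0771). In both lists 0 members passed when adjusted over the list alone.

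**Figure D3:**
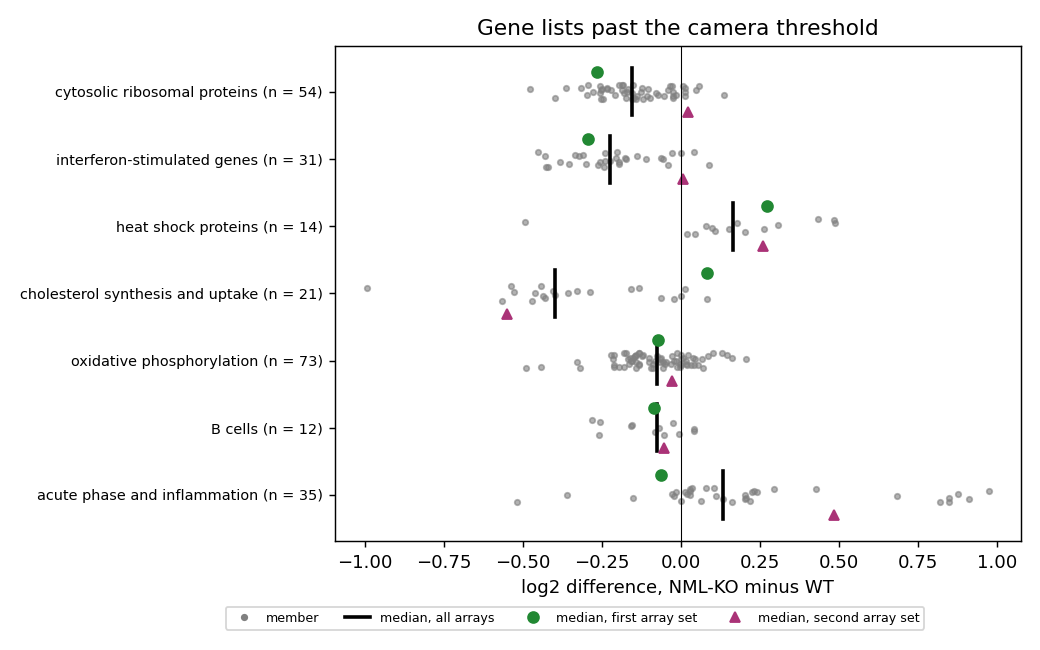
Log2 difference (NML-KO minus WT) of each measured member (grey points) of the 7 lists past the camera threshold, with the median over all arrays (bar) and the medians within the first array set (circle) and the second (triangle). Heat shock proteins had medians of 0.27 and 0.26 in the array sets, whereas cytosolic ribosomal proteins had -0.27 and 0.023.

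Lists tied to the known role of nucleomethylin did not pass. These lists hold messenger RNAs of proteins, and the ribosomal RNA precursor Rn45s was not among the measured members. They therefore do not show whether silencing of ribosomal RNA genes differed. The transcription machinery of RNA polymerase I had a median of 0.043 over 19 members (camera adjusted p = 0.538), rRNA processing and ribosome assembly 0.00046 over 50 (0.75), and p53 targets, which respond to nucleolar stress, 0.0062 over 22 (0.529). A list drawn up as partners of nucleomethylin (Sirt1, Sirt7, Suv39h2, Kdm2a, Kdm2b, Phf8, Kat5 and Mybbp1a) had a median of 0.0048 over 8 members and a mean of -0.017 (camera adjusted p = 0.75). Suv39h1 was in this list but was not measured, and whether each member binds nucleomethylin was not checked. With the array set in the model these medians were 0.011 for RNA polymerase I, -0.0064 for rRNA processing, 0.029 for p53 targets and -0.041 for the partners (camera adjusted p = 0.855, 0.855, 0.171 and 0.461). The RNA polymerase I median was -0.081 in the first array set and 0.065 in the second (camera adjusted p = 0.00977 in the second), and with array weights this list and rRNA processing both passed (0.0419 for each). The rRNA processing median was -0.048 in the first array set and 0.028 in the second (camera adjusted p = 0.0494 in the second). With an estimated correlation, the second-set adjusted p was 0.599 for RNA polymerase I and 0.728 for rRNA processing, and that with array weights was 0.795 for both. Polr2e, a subunit shared by the RNA polymerases, was 1.17-fold lower (unadjusted p = 0.0186 by limma), with WT 3 apart from the other WT livers, and Kat5, an acetyltransferase gene, was 1.18-fold lower (unadjusted p = 0.0301 by limma). Their log2 differences were -0.38 and -0.36 in the first array set and -0.035 and -0.076 in the second.

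Metabolic lists that did not pass had these medians over all arrays, with camera adjusted p in parentheses. Fatty acid and triglyceride synthesis had -0.051 (0.529), fatty acid oxidation and PPARA targets -0.046 (0.304), gluconeogenesis, glycogen and insulin response 0.044 (0.226), bile acid synthesis and transport -0.015 (0.529) and xenobiotic metabolism -0.033 (0.75). Within the second array set 4 of these were lower, fatty acid synthesis at -0.16 (0.00392), fatty acid oxidation at -0.15 (4.69e-05), bile acid synthesis at -0.21 (1.73e-05) and xenobiotic metabolism at -0.069 (0.0329), but adjusted p = 0.599 with an estimated correlation for each. In the first array set their medians were 0.10, -0.034, 0.069 and -0.00081, and none passed. With 1 array left out, the sign turned for fatty acid synthesis (-0.10 to 0.029), fatty acid oxidation (-0.10 to 0.020) and xenobiotic metabolism (-0.085 to 0.022). It did not turn for gluconeogenesis or bile acid synthesis. The circadian clock list had a median of 0.20 (0.0842), but -0.0042 with the array set in the model (0.691), -0.12 in the first set and 0.063 in the second (0.0149). It passed without WT 1 (median 0.26, 0.00622), WT 2 (0.41, 0.00688) or NML-KO 4 (0.36, 0.0296), and with array weights (0.42, 0.000618), dim genes left out (0.0141) or median centring (0.0351). Its median was 0.088 without WT 3, 0.092 without WT 5, 0.075 without NML-KO 1 and 0.31 without NML-KO 5, and with an estimated correlation its adjusted p was 0.818 over all arrays and 0.599 in the second set. Its member Alas1, the first enzyme of haem synthesis, differed by 1.46 (SE 0.73), or 1.03 (SE 0.32) with the array set in the model, 0.26 in the first set and 1.79 in the second. ER stress and amino acid response genes had a median of 0.10 (0.0573) and cell division genes 0.039 (0.188). Within the second array set ER stress had a median of 0.31 (1.46e-07), against 0.015 in the first, and cell division 0.064 (0.0145), against 0.016, but adjusted p = 0.599 with an estimated correlation for each. The ER stress list passed without WT 2 (median 0.11, camera adjusted p = 0.0443), WT 3 (0.16, 0.00712), NML-KO 2 (0.18, 0.00347) or NML-KO 3 (0.20, 0.000577), and had a median of 0.028 without NML-KO 4 and 0.048 without NML-KO 5. Median centring (0.0331), array weights (0.0334) and leaving out dim genes (0.0120) also put it past the camera threshold. With array weights and an estimated correlation its adjusted p was 0.795. Cell division passed without WT 5 (0.0286) or NML-KO 2 (0.0129), fatty acid oxidation without WT 3 (median -0.10, 0.0243) or NML-KO 1 (-0.090, 0.0460), and gluconeogenesis without WT 2 (0.11, 0.0191). Gluconeogenesis also passed with array weights (camera adjusted p = 0.0474), but not with an estimated correlation as well (0.767). With 1 array left out and an estimated correlation, 0 of the 34 lists passed in any of the 10 fits, with a smallest adjusted p of 0.148. With the array set in the model, the ER stress list passed (median 0.16, camera adjusted p = 0.00152), as did fatty acid oxidation (median -0.098, 0.00435), but neither with an estimated correlation as well (adjusted p = 0.718 for both). Male-biased liver genes had a median of 0.029 (0.374), female-biased genes 0.034 (0.226), pericentral hepatocyte genes -0.015 (0.529) and periportal hepatocyte genes 0.0058 (0.604). Periportal genes had a median of -0.089 in the first array set and 0.065 in the second (camera adjusted p = 0.0149 in the second; adjusted p = 0.599 with an estimated correlation). Male-biased genes had a median of 0.47 in the first array set and -0.22 in the second (camera adjusted p = 6.67e-06 and 0.00977), but adjusted p = 0.858 and 0.599 with an estimated correlation. WT 2 had the lowest level of this list, 3.28 above the mean of all genes on the log2 scale against 3.92 to 4.54 in the other livers, and without WT 2 the median was -0.15 (camera adjusted p = 0.0069). Without WT 2, female-biased genes (median 0.10, 0.0102) and pericentral genes (-0.075, 0.0265) also passed, and male-biased genes passed without WT 5 (0.10, 0.0453). Pericentral genes had a median of 0.14 in the first array set and -0.22 in the second (0.0165 and 0.00607), with adjusted p = 0.858 and 0.599 with an estimated correlation.

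Of the cell type markers, those of B cells were lower, with 10 of 12 members below 0 and a median of -0.076 (camera adjusted p = 0.0228; adjusted p = 0.762 with an estimated correlation). Blk, a kinase of B cells, was 1.11-fold lower and Cd79a, part of the B cell receptor, 1.22-fold lower. Both were dim, at log2 values of 5.27 to 5.63 for Blk and 4.47 to 5.36 for Cd79a. The mean of the list lay below that of all genes in every liver, by -1.37 to -1.07 on the log2 scale. In this list 0 members passed when adjusted over the list alone. The median was -0.084 in the first array set and -0.054 in the second, and the call was lost without WT 2 (camera adjusted p = 0.130) or NML-KO 5 (0.0748). The other 11 marker lists did not pass. Hepatocyte markers had a median of -0.00078 (camera adjusted p = 0.75), Kupffer cells and macrophages -0.11 (0.656), sinusoidal endothelium -0.077 (0.0573), stellate cells and fibroblasts 0.084 (0.0573), bile duct cells -0.036 (0.529) and T and NK cells -0.039 (0.426). Markers of neutrophils and marrow granulocytes had a median of 0.027 (0.127), red cells and their precursors 0.016 (0.249), exocrine pancreas 0.046 (0.0573), fat tissue -0.20 (0.278) and gall bladder, stomach and gut lining 0.0077 (0.374). With the array set in the model, the stellate cell list passed (median 0.082, camera adjusted p = 0.0447; adjusted p = 0.718 with an estimated correlation). Within the second array set, markers of sinusoidal endothelium (median -0.15, camera adjusted p = 1.73e-05), stellate cells (0.11, 0.0105), neutrophils (0.041, 0.0328) and Kupffer cells (0.22, 0.00264) passed, against -0.00070, 0.042, -0.023 and -0.21 in the first, but with an estimated correlation the second-set adjusted p was 0.599 for the first 3 and 0.602 for Kupffer cells. Kupffer markers passed without WT 1 (median -0.23, camera adjusted p = 0.0188) or NML-KO 4 (-0.29, 0.00573) and had a median of 0.054 without NML-KO 2. Sinusoidal endothelium passed without WT 1 (-0.13, 0.000411) or NML-KO 3 (-0.15, 3.82e-06), and neutrophil markers without NML-KO 1 (0.045, 0.0393). Stellate cells passed without WT 2, WT 3, NML-KO 1 or NML-KO 2 (0.0154, 0.00712, 0.00207 and 0.0402), and exocrine pancreas without WT 1, WT 3, NML-KO 4 or NML-KO 5 (0.0181, 0.0385, 0.0296 and 0.0258). None of these calls held with an estimated correlation. Sinusoidal endothelium also passed with array weights (camera adjusted p = 0.0115, but 0.795 with an estimated correlation) and with all probe sets (0.0382). Median centring put stellate cells (0.0351) and exocrine pancreas (0.0415) past the camera threshold. The fat tissue median was -0.049 without WT 2, in which these markers averaged 1.09 above the mean of all genes against 0.013 to 0.18 in the other 9 livers. Of the 27 lists that did not pass over all arrays, 2 passed within the first array set alone and 16 within the second, and 0 in either with an estimated correlation.

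Genes next to Rrp8 on chromosome 7 were examined because a targeted allele can carry flanking DNA of the strain in which it was made. Of the 200 tested genes nearest to Rrp8, 100 on each side in gene order, 0 passed the adjusted threshold, and 0 of the other tested genes did, so that the planned two-sided Fisher's exact test had nothing to compare. At an unadjusted p below 0.05 there were 7 of these 200 genes (3.50%) against 2.69% of 19652 others. Many of the 200 are olfactory receptor genes, but of the 7 only Olfr646 is one. The 3.50% therefore understates the share among the other genes near Rrp8. Neither share was calculated without that family, so they do not show how those other genes compare. The sex markers had the pattern of males in all 10 livers and did not separate the genotypes. Xist, transcribed from the inactive X chromosome of females, lay between 4.60 and 4.99 in all 10 livers. The Y-linked genes Eif2s3y, Kdm5d and Uty had mean log2 intensities of 8.24, 7.45 and 7.52 in WT and 8.33, 7.49 and 7.44 in NML-KO livers. In single livers they lay between 8.08 and 8.54, 7.27 and 7.59, and 7.11 and 7.63. Nnt, which is partly deleted in the C57BL/6J strain, averaged 8.86 ± 0.54 (SD, n = 5) in WT and 8.78 ± 0.32 (SD, n = 5) in NML-KO livers, which overlapped. In the first array set, however, both WT livers (9.47 and 9.44) lay above the 3 NML-KO livers (8.74, 9.30 and 8.59), a difference of -0.58, and in the second the difference was 0.16.

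**Figure D4:**
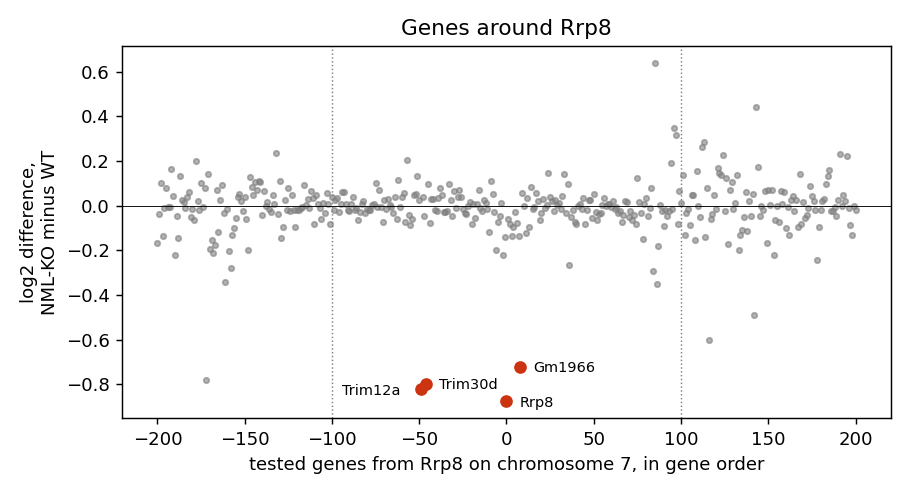
Log2 difference (NML-KO minus WT) of Rrp8 and the 200 tested genes on each side of it on chromosome 7, in gene order, with dotted lines at 100 genes. Red labelled points have an unadjusted limma p below 0.01: Rrp8 at -0.88, Trim12a at -0.82, Trim30d at -0.80 and Gm1966 at -0.72.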

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

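The test of the array sets was chosen after the list results had been seen, and what the planned estimated correlation should show was written after its result; the counts of other splits of the arrays were chosen before those counts were seen, except that for the 0 genes past the threshold. Single arrays apart from their group were also sought in the 27 lists that did not pass after those results had been seen.

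The 7 lists past the camera threshold are a number that other splits of the arrays often gave. Of 100 splits of the 10 arrays into 5 and 5, the real one counted in these and all later numbers of splits, 90 put at least 7 lists past the threshold, and the highest of the other splits had 18, so chance could not be excluded; the split that follows the array sets gave 10. An unequal share of the array sets, with 2 WT against 3 NML-KO livers in the first, is argued against only weakly as the whole source. With the array set in the model 7 of the 7 lists stayed past the threshold in the same direction. The median of oxidative phosphorylation shrank from -0.076 to -0.038 and that of cholesterol synthesis from -0.40 to -0.22. This used the preset correlation, with which 90 of 100 splits gave as many lists. With an estimated correlation as well, 0 lists passed (smallest camera adjusted p = 0.515). Medians of cholesterol synthesis and acute phase genes had the other sign in the first set, and those of ribosomal proteins and interferon-stimulated genes in the second. List members that vary together between animals of 1 genotype remain a candidate source, since 0 of the 7 lists passed with the correlation estimated per list. An effect of the missing nucleomethylin on these groups stays open.

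For the 0 genes past the threshold the splits decide nothing, since 100 of 100 must have at least 0; the highest other count was 2797. The 539 genes with an unadjusted p below 0.05 were matched or exceeded by 70 of 100 splits, with a highest other count of 5428, so chance could not be excluded. Both highest counts came from the split that follows the array sets, which had to be large because the sets were made from the same values; with the array set in the model the counts were 0 and 870.

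In 17 of 198 groups of 5 arrays, 1 array lay far from the other 4, measured as its gap to the nearest divided by the range; chance alone would give about 9.9 at 1 in 20. Among WT livers, WT 2 stood apart for Cib3 (7.53 against 6.63 to 6.87, ratio 0.731) and Nudt7 (11.1 against 12.0 to 12.3, ratio 0.762). WT 1 stood apart for Strn4 (8.18 against 7.88 to 7.93, ratio 0.807) and Xist (4.99 against 4.75 to 4.79, ratio 0.820). WT 3 stood apart for Polr2e (7.65 against 7.85 to 7.90, ratio 0.783) and Csad (8.93 against 9.95 to 10.1, ratio 0.844), and WT 4 for Sesn2 (6.50 against 6.71 to 6.78, ratio 0.753). Among NML-KO livers, NML-KO 4 stood apart for Ephx1 (10.8 against 11.2 to 11.3, ratio 0.777), Cyp3a44 (7.10 against 7.74 to 7.98, ratio 0.732) and Plk1 (5.92 against 5.24 to 5.37, ratio 0.815), and NML-KO 5 for Kdm5d (7.27 against 7.50 to 7.59, ratio 0.726). Of the list means, taken above the mean of all genes, WT 2 stood apart for male-biased genes (3.28 against 4.18 to 4.54 in the other WT livers, ratio 0.714), female-biased genes (-0.19 against -0.78 to -0.63, ratio 0.737) and fat tissue markers (1.09 against 0.020 to 0.18, ratio 0.846), and WT 1 for p53 targets (0.23 against 0.37 to 0.39, ratio 0.832). NML-KO 4 stood apart for pericentral genes (2.90 against 3.20 to 3.26, ratio 0.843) and for neutrophil and marrow granulocyte markers (-0.82 against -1.45 to -1.29, ratio 0.751).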

How the results depend on the processing

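The alternatives with array sets, the permuted list means and the unadjusted p near Rrp8 were chosen after seeing the data. Rrp8 stayed lower, with an exact permutation p or limma unadjusted p below 0.05, in all alternatives run, from -0.97 to -0.76, and from -0.96 to -0.82 with 1 array left out. The count of genes past the threshold was 0 to 1 with 1 array left out, the 1 being Rrp8 without NML-KO 4, and 0 in the other fits, while 539 had an unadjusted p below 0.05. Near Rrp8, 7 genes had an unadjusted p below 0.05 and 3 below 0.01. The number of lists past the threshold, 7, was 11 with median centring, 12 with array weights, 5 to 12 with 1 array left out and 19 within the second array set. It was 0 with an estimated correlation (also with the array set block), with fry and with permutation of list means, over all arrays or within array sets. The permutation count decides little. Its smallest possible p was 0.00794 over all arrays and 0.01 within array sets. Adjusted over 34 lists, such a p can pass only if several lists reach it together. Quantile normalization left 5, losing oxidative phosphorylation (adjusted p = 0.0793) and acute phase (0.0616); oxidative phosphorylation also lost its call with dim genes left out (0.0764), and acute phase with array weights (0.116) and all probe sets (0.0649). The cause was not tested for the scalings; the smaller sets have fewer arrays. The median had another sign in 12 of 34 lists within the first array set: cholesterol synthesis 0.083, acute phase -0.063, pericentral 0.14, periportal -0.089, fatty acid synthesis 0.10, bile acids 0.069, female-biased -0.076, neutrophils -0.023, clock -0.12, RNA polymerase I -0.081, rRNA processing -0.048 and partners -0.10. It did in 9 within the second: ribosomal proteins 0.023, interferon-stimulated genes 0.0068, male-biased -0.22, Kupffer cells 0.22, red cells -0.046, exocrine pancreas -0.015, T and NK cells 0.015, hepatocytes 0.021 and partners -0.020. With 1 array left out, male-biased genes ran from -0.15 (without WT 2) to 0.10 and acute phase genes from -0.10 to 0.25; of 340 such list values, 29 gained and 11 lost a call. Same-numbered samples did not all deviate together (correlations of 0.44, 0.26, -0.42, 0.35 and 0.54), and 1 of 5 WT livers correlated best with its own number. The negative value belongs to replicate 3, the only number whose WT and NML-KO livers lie in different array sets. The correlations thus follow the array sets and cannot tell whether the numbers pair the samples. With a replicate block, 0 genes and 8 lists passed (B cells did not, at 0.0668; the clock list at 0.0313 and sinusoidal endothelium at 0.0454 did), Rrp8 differed by -0.88, and 0 genes near Rrp8 passed. The 1458 values of other named genes never crossed the threshold; 12 changed sign. Signal over background is unknown for these values, which limits what dim genes can show.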

Other observations

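The tests of the clock genes, of a difference in array handling and of the share of genes near Rrp8, with the interaction, the balanced splits and the ratio of each gene there, were chosen after the values had been seen; the test of the median with interferon-stimulated genes and that of other splits near Rrp8 were chosen before.

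Of the 34 lists, clock transcripts had the largest share of genes that followed the array sets. With the clock list left out when the sets were made, 18 of 23 measured clock genes did not overlap between the 5 arrays of the first set and the 5 of the second, 14 higher in the first and 4 in the second. Among other lists, 13 of 35 acute phase genes did not overlap, 12 of them higher in the second set, and 24 of 73 oxidative phosphorylation genes, 19 of them higher in the second. Fatty acid oxidation went the other way, with 10 of its 11 such genes higher in the first set. Nr1d1, which encodes the repressor REV-ERB alpha, varied inside the second set, at 9.86 in WT 3 and 9.41 in WT 5 against 7.24 in WT 4, 7.92 in NML-KO 4 and 7.05 in NML-KO 5.

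A candidate explanation for the array sets is a different time of day at dissection. Of all clock genes, 78.3% did not overlap between the sets, and genes of opposite phase went opposite ways: Dbp, Tef, Per1, Per2, Per3, Ciart, Usp2 and Nr1d2 were higher in the first set, and Arntl, Clock, Cry1 and Nfil3 in the second. These genes were picked after their values had been seen, and Nr1d1 and Hlf, which overlapped between the sets, were not among them. A difference in array handling as the whole cause is argued against, because the share of 78.3% was 6.43 times the 12.2% of all genes. That ratio may overstate the contrast, since all genes include dim ones, which were not filtered. The next largest shares among the lists were 37.1% for acute phase genes and 36.8% for hepatocyte markers. Handling that coincided with the time of dissection stays open, as the labels give neither. No biological explanation from the study's groups was tested for the sets, which both hold both genotypes.

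Among the 200 genes nearest to Rrp8, 3 had an unadjusted p below 0.01, all lower in NML-KO livers: Trim12a (-0.82), which the rule named, and Trim30d (-0.80) and Gm1966 (-0.72), chosen after their values were seen. The Trim genes have close relatives beside them that their probe sets may also read, which was not tested. Many of the 200 are olfactory receptor genes, which the shares given next include, so the share of the 200 understates that among the others of them. Flanking DNA of another strain was not decided and stays open: 1.5% of these genes against 0.30% of others gave a two-sided Fisher's exact p of 0.0247, but the limit of 0.01 was set after these genes had been seen, so that this p restates what prompted it, and it was 0.185 with the array set in the model and 0.505 at an unadjusted p below 0.05; at p below 0.01 it was 0.00378 for 50 genes on each side, 0.129 for 200 and 0.0209 for the whole chromosome (0.0382, 0.0030 and 0.00739 with the array set in the model). Such DNA would be in every NML-KO liver, while the differences in the first and second array set were -0.21 and -1.44 for Trim30d (unadjusted p = 0.000651 and adjusted p = 0.717 for limma's interaction), -0.52 and -1.22 for Trim12a (unadjusted p = 0.0799) and -0.64 and -0.78 for Gm1966 (unadjusted p = 0.733). The planned count could not exclude chance, because 9 of 100 splits of the arrays, the real one included, had at least 3 such genes. The highest other count was 11, in the split that follows the array sets. Of the 81 splits that hold the array sets in the real balance, 3 (3.70%) had at least 3, the real one included. That smaller share leaves chance undecided, since the balanced count was chosen after the values had been seen. Lower interferon-stimulated genes are argued against as the source for the 3 genes as a set, whose median difference with the mean of that list in the model was 1.05 times its size without it (0.872 to 1.21 with 1 array left out), and for Trim12a (1.02 times) and Trim30d (1.09 times) by themselves, but stay open for Gm1966, at 0.805 times (0.596 to 0.875 with 1 array left out). Lrrc32, Strn4 and Ttll13, also lower with an unadjusted limma p below 0.01, lie on the same chromosome but outside the 200 genes. Whether flanking DNA reached them was not tested.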
